A study of Danio rerio with 15 samples.

How the data were processed

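Gene expression was measured in whole brains of 15 adult zebrafish on Affymetrix GeneChip arrays, 1 fish per array. Total RNA was extracted with Trizol, and biotin-labelled cRNA was made with a 3′ amplification one-cycle kit, per the labels. The deposited values are log2 expression values per probe set, made by the authors with RMA and the affy software. RMA corrects the background, brings all arrays to 1 distribution of intensities and summarises the probes of each probe set. The versions of both tools, and whether the values were normalised over more than the 15 deposited arrays, are not given in the sources used here. The deposited log2 values were used as they are, with no further scaling.

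The table held 15617 probe sets. Of these, 115 control probe sets of the manufacturer were left out of the tests, which left 15502. No filter on low signal was applied. The annotation of the array assigned 1 gene symbol to 10795 of the tested probe sets, several symbols to 135 and none to 4572. The symbols named 8793 genes, of which 1539 had more than 1 probe set. Probe sets are named by gene symbol, and no coordinates are given, because the only coordinates at hand belong to the GRCz12tu assembly and not to the probes. For arrays, the number of fish limits the precision. The median residual SD of a probe set was 0.169 log2 units.

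Groups were taken from the sample labels: females on the control diet (3 fish), females on the selenium diet (4), males on the control diet (4) and males on the selenium diet (4). No label gave a batch, and each fish had a number of its own, so no block was fitted. A linear model of the 4 group means was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (11 residual degrees of freedom, 13.8 in all after moderation). It gave 5 comparisons: the diet effect in females, the diet effect in males, their mean, their difference, and the sex difference averaged over the diets. The p values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and a probe set was called at an adjusted p under 0.05. All tests were two-sided.

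The tests, 34 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists covered selenoproteins, selenocysteine synthesis and selenium handling, antioxidant and glutathione genes, heat shock and cytosolic chaperones, endoplasmic reticulum stress, the glucocorticoid response, immediate early genes, the circadian clock, cholesterol synthesis, the cell cycle, sex steroid and reproductive genes, metal and iron handling, inflammation and interferon, methionine and one-carbon metabolism, p53 and apoptosis, and glycolysis. Further lists held cytosolic ribosomal proteins, mitochondrial ribosomal proteins, the respiratory chain, the proteasome and translation factors. Marker lists stood for neuronal and synaptic genes, monoamine genes, oligodendrocytes and myelin, radial glia and astrocytes, microglia and macrophages, erythrocytes, endothelium and vessels, meninges and extracellular matrix, ependyma and choroid plexus, pituitary hormones, the pineal organ, retina and lens, and skeletal muscle.

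Each list was tested with limma's camera, which compares the members with all other genes, at a preset correlation between genes of 0.01, with the brightest probe set of each gene and at least 5 measured genes. The p values were adjusted over the lists within each comparison, and a list was called at an adjusted p under 0.05. The same lists were tested with camera at a correlation estimated from the data, with limma's fry, and with an exact permutation test of the mean over members, which takes the fish as the unit. That last test used all 35 assignments of diet in females, all 70 in males, and all 2450 combined assignments for the other 3 comparisons. A member of a list was also tested with p values adjusted over the list alone.

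In each comparison the text may name, among genes past the threshold, the 12 with the largest rise and the 12 with the largest fall. Where fewer than 20 passed, all of them and those with the smallest p, up to 20 in all, may be named. Any selenoprotein and up to 4 members of smallest p of each other list may be named too.

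The model was tested on simulated data with the same design, in which genes varied independently and 200 probe sets were changed in each comparison. A true log2 difference of 1 was recovered for 86.1% of the changed probe sets in females, 89.1% in males, 95.2% for the mean of both sexes, 74.6% for the difference between the sexes and 96.5% between females and males. These shares say nothing of smaller differences, such as the median of 0.58 among the probe sets later called between the sexes. They hold for 200 changed probe sets. Where fewer change, the Benjamini-Hochberg threshold is stricter, so the shares can overstate what the data could recover. A shift of 0.2 log2 units in all members of the 2 lists simulated, of 24 and 84 genes, was recovered in each comparison. Smaller lists were not simulated.

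Alternatives left out the dimmest 25% or 50% of the probe sets, centred each array on its median, normalised by quantiles again, and used array weights, a trended and robust prior variance, gene means, a threshold of 0.1, other models of diet and sex, or the mean 3′ minus 5′ difference of the actin and gapdh control probe sets as a covariate. Each array was also left out in turn. Added after the data were seen were the gapdh difference alone as a covariate, the muscle and retina list means as covariates, the exact permutation of all lists, for the list tests the scalings of the arrays (except median-centring for selenoproteins) and the actin and gapdh covariate, and fits without the arrays that had high muscle or retina gene signal. Where settings are counted, those that cannot speak to a list are left out. In 1 sex the exact test of the lists can call none unless 20 of the 34 reach its smallest p. Muscle, retina and pineal genes are not tested by covariates made of such genes (for muscle also the actin control, a muscle actin) or without fish chosen for their signal. A fish was compared with the others of its group of 4 by Dixon's test.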

Results

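Whole-brain RNA of 15 adult zebrafish, each about 1 year old and of the strain labelled Transgenic Mosaic 1, was profiled to describe the response of the brain to a short selenium supplement. The fish were fed for 14 days a control diet with 1.4 ppm selenium or a diet supplemented with sodium selenite, with 5.6 ppm. The arrays held 3 females and 4 males on the control diet and 4 females and 4 males on the selenium diet. The design text describes equal numbers of both sexes in each diet, so 1 more female on the control diet was planned or used, and it is not analysed here. The median of an array lay between 7.22 and 7.33 log2 units, and the correlation across probe sets of any 2 arrays lay between 0.979 and 0.992. The number of fish limits the precision. The 95% confidence interval of a diet difference reached a median of 0.27 log2 units to either side in females and 0.25 in males.

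Selenoproteins carry selenium as selenocysteine, and the diet comparison asked first whether their genes responded to the supplement. Of 24 selenoprotein genes measured, read by the brightest probe set of each, 13 were higher and 11 lower in females on selenium. The median log2 difference was 0.0056. In males 17 were higher and 7 lower, with a median of 0.036. By these probe sets, the gene furthest from 0 by its test in females was gpx1a, a cytosolic glutathione peroxidase. Its log2 difference was -0.34 ± 0.11 (SE, n = 4 and 3). Next came selenow1 with -0.21 ± 0.07, selenoo1 with -0.33 ± 0.13 and selenon with -0.23 ± 0.10. In males the gene furthest from 0 was gpx4b, a phospholipid hydroperoxide glutathione peroxidase, with 0.43 ± 0.16 (SE, n = 4 and 4). Probe sets of 1 gene could disagree. In females a dim probe set of msrb1a, at 3.59 in controls, stood at 0.40 ± 0.11, with a smaller unadjusted limma p than gpx1a (0.0037 against 0.0078). Other probe sets of msrb1a read -0.20 and, for the brightest, 0.05. For selenot2 the brightest read 0.19 and the other -0.22. The plasma selenium carrier selenop stood at -0.04 in females, with a 95% confidence interval from -0.29 to 0.21, and at 0.11 in males, with an interval from -0.12 to 0.34. For gpx1a the female minus male difference of the diet effect was -0.49 ± 0.15.

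None of these genes passed the test. With limma, 0 selenoproteins passed in either sex over all probe sets and 0 adjusted over the list alone, where the smallest value was 0.115 for both gpx1a and selenow1 in females, 0.482 for gpx4b in males and 0.134 for gpx1a in the difference between the sexes. At an unadjusted p under 0.05 there were 4 genes in females and 1 in males, by the brightest probe sets. Camera gave the list an adjusted p of 0.396 in females and 0.331 in males, fry gave 0.624 and 0.425, and the exact permutation p was 0.286 and 0.257. In females, averaged over the sexes and between the sexes the median of the list lay above 0 while its test pointed down, and the mean was -0.035 in females, 0.0022 averaged over the sexes and -0.041 between the sexes. The median of the list in females was -0.013 when arrays were normalised by quantiles again. The smallest adjusted camera p over the 5 comparisons was 0.159 for selenoproteins, 0.83 for the 8 measured genes of selenocysteine synthesis and selenium handling, and 0.175 for 26 antioxidant and glutathione genes.

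**Figure D1:**
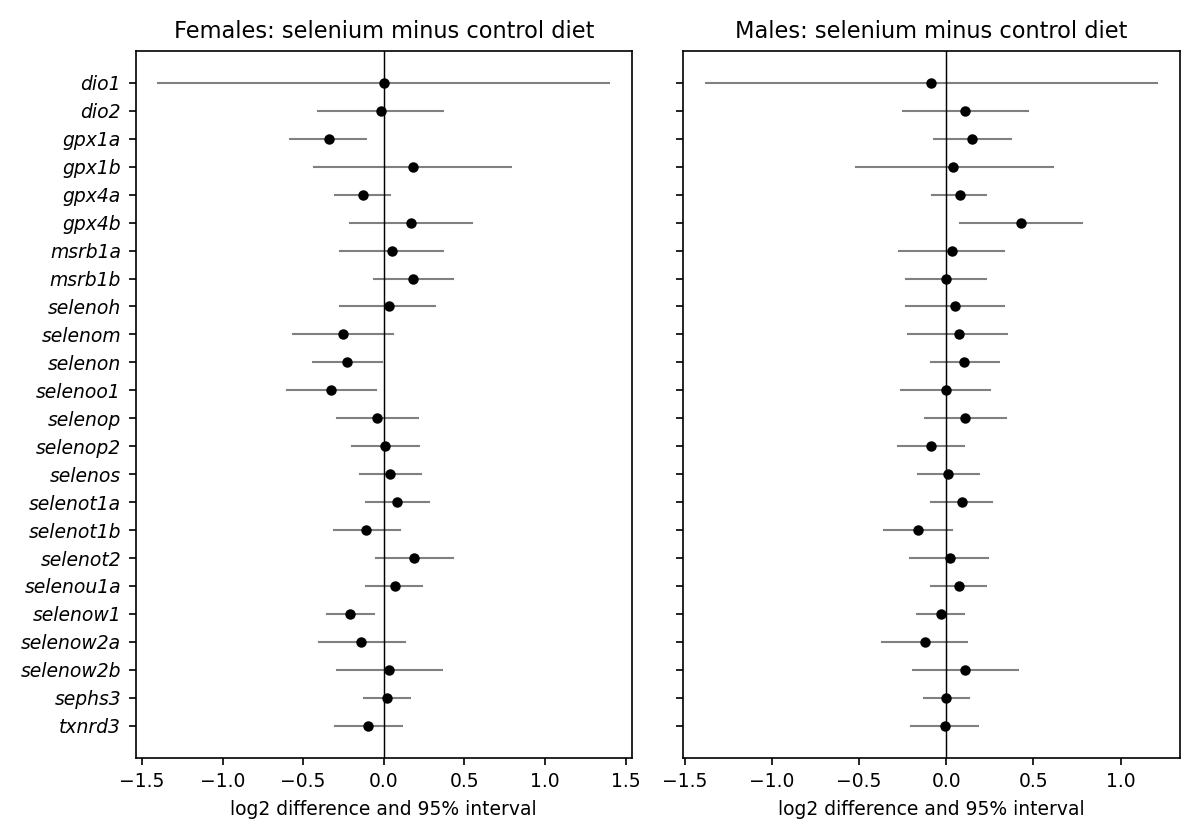
Difference between the selenium and the control diet for the 24 measured selenoprotein genes in females (left, 4 and 3 fish) and males (right, 4 and 4 fish), in log2 units. Points are estimates from the brightest probe set of each gene and lines are 95% confidence intervals; the interval of gpx1a in females runs from -0.58 to -0.11, and 0 genes passed the adjusted test in either sex.

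The response of the female brain to the diet was examined over all genes. Among those with the smallest p, papss2b, which makes the activated sulphate donor of the cell, stood at a log2 difference of -0.86 ± 0.16 (SE, n = 4 and 3) and mcur1, a regulator of mitochondrial calcium uptake, at -0.54 ± 0.10. The DNA damage kinase gene chek2 stood at -1.10 ± 0.25, ranbp9 at -1.13 ± 0.24, lrrc8aa, a subunit of the volume-regulated anion channel, at -1.31 ± 0.28, and the chaperone cofactor gene ubxn4 at 1.69 ± 0.38. The hydroxylase gene of coenzyme Q synthesis, coq7, stood at -0.48 ± 0.11, the AP-1 gene fosl1b at -0.78 ± 0.16 and the Notch-related repressor her3 at -0.66 ± 0.14. Chosen by their p, these genes part the fish by selection: all 4 females on selenium lay beyond all 3 controls, except for lrrc8aa, where 3 did. None passed: limma called 0 of 15502 probe sets, the smallest adjusted p was 0.292, and 1282 probe sets had an unadjusted p under 0.05, where 775 are expected by chance. The count was 5 without female control replicate 3 and 3 without female selenium replicate 2.

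The 84 respiratory chain genes encode subunits of the mitochondrial complexes of oxidative phosphorylation, with some assembly factors and inhibitors. As a group they were lower in females on selenium, with 59 members lower and a median log2 difference of -0.045. Centring each array on its median turned this to 0.016, by moving all probe sets alike by 0.061. Examples are sdhb with -0.25 ± 0.07, uqcrfs1 with -0.25 ± 0.09 and the assembly factor gene ndufaf2 with -0.26 ± 0.09. The 14 glucocorticoid response genes were higher as a group, with a median of 0.18 and 13 members higher, among them pck1 with 0.29 ± 0.12, cebpb with 0.35 ± 0.15 and ddit4 with 0.20 ± 0.09. No single member of either list passed, over all probe sets or adjusted over the list alone. The adjusted camera p was 0.0208 for the respiratory chain and 0.0365 for the glucocorticoid response. Both calls were lost with the correlation estimated from the data, with adjusted p = 0.913 with an estimated correlation for each, and fry called 0 lists. They also ended with arrays centred on their medians (adjusted p = 0.243 for the respiratory chain and 0.131 for the glucocorticoid response) and with the gapdh difference as a covariate (0.205 and 0.365). With that covariate the respiratory chain median stayed near its value, at -0.042, and the glucocorticoid median was 0.035 in place of 0.18. Of 12 settings other than single fish left out, the respiratory chain call ended in 8 and the glucocorticoid call in 10. The respiratory chain call ended without female control replicate 1 (adjusted p = 0.508) or female selenium replicate 2 (0.151). The glucocorticoid call ended without female control replicate 1 (0.387), female control replicate 2 (0.0825), female selenium replicate 2 (0.1) or female selenium replicate 3 (0.183). The respiratory chain median was -0.022 without female control replicate 1, -0.069 without female control replicate 2, -0.026 without female selenium replicate 2 and -0.068 without female selenium replicate 4, and the glucocorticoid median was 0.10 without female control replicate 2. The gapdh control probe sets read the 3′ end above the 5′ end by 1.59 ± 0.24 log2 units (SD, n = 4) in females on selenium and by 1.19 ± 0.37 (n = 3) in controls (exact permutation p = 0.143). Skeletal muscle genes had a list mean of 6.38 ± 0.13 in the 4 females on selenium and 6.01 ± 0.14 in the 3 controls, with all 4 above all 3 (exact permutation p = 0.0286, the smallest the 35 assignments can give; adjusted camera p = 0.134).

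In males the diet effect was examined in the same way, with 4 fish on each diet. The gene with the smallest p was ckmt2a, a mitochondrial creatine kinase of striated muscle, at a log2 difference of 2.37 ± 0.39 (SE, n = 4 and 4). Among the 20 smallest was atp2a1l, a calcium pump of the sarcoplasmic reticulum, at 2.92 ± 0.76. The keratin gene krt15 stood at 1.41 ± 0.33. The nuclear import gene kpna3 stood at -0.33 ± 0.07, the transcription factor genes sp8b at -0.50 ± 0.11 and crema, a regulator of cAMP-driven transcription, at -0.58 ± 0.13, and the natriuretic peptide receptor gene npr3 at -0.42 ± 0.11. These genes, too, were chosen by their p, and all 4 males on selenium lay beyond all 4 controls for each. None passed: limma called 0 of 15502 probe sets, the smallest adjusted p was 0.478, and 811 probe sets had an unadjusted p under 0.05, where 775 are expected by chance. Without male selenium replicates 1, 2 and 4 together, which leaves 1 male on selenium whose spread is assumed to be that of the other groups, the count was 15. Without the 4 arrays of highest retina signal it was 6.

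Skeletal muscle genes were higher as a group in males on selenium, with 35 of 36 members higher and a median log2 difference of 1.03. The creatine kinase gene ckma stood at 1.80 ± 0.55 and the muscle enolase gene eno3 at 0.65 ± 0.18. Over all probe sets 0 members passed, and 8 passed adjusted over the list alone. Retina and lens genes were higher as well, with 30 of 35 members higher and a median of 1.14, among them the cone genes gnb3b with 2.21 ± 0.80, opn1lw1 with 2.11 ± 0.77 and opn1sw2 with 1.97 ± 0.77. The size of the signal differed between fish, and 3 of the 4 males on selenium lay above all 4 male controls in the muscle list and 2 in the retina list. In male selenium replicate 1 the muscle list lay 2.47 log2 units above its mean over all fish, in replicate 3 0.69, in replicate 2 0.23 and in replicate 4 -0.31. The retina list lay 1.96 above its mean in replicate 2 and 1.55 in replicate 4, against -0.33 in replicate 1 and -0.47 in replicate 3, and it also lay at 0.68 in female control replicate 2 and 0.49 in female selenium replicate 2. Pineal genes, of which 3 of 10 are also in the retina list, had a median of 0.62, with gngt1 at 2.77 ± 1.80. Meningeal and matrix genes had a median of 0.17, with the keratin gene krt5 at 2.24 ± 0.96 and sparc at 0.27 ± 0.13. That list also holds the keratin genes krt4, krt8 and krt18a.1 and the epithelial gene epcam, so it is not specific to meninges. The adjusted camera p was 3.31e-20 for muscle, 3.6e-09 for retina, 0.00205 for pineal and 0.00976 for meningeal genes. All 4 calls were lost with the correlation estimated from the data: adjusted p = 0.372 with an estimated correlation for muscle, 0.471 for retina, 0.516 for pineal and 0.471 for meningeal genes. The exact permutation p was 0.0571 for muscle and 0.2 for retina. Over all arrays left out singly, the median of the muscle list ran from 0.42, without male selenium replicate 1, to 1.39. That of the retina list ran from 0.62, without male selenium replicate 2, to 1.61. The pineal call ended without male selenium replicate 4 (adjusted p = 0.219), at a median of 0.12, and the meningeal call without male control replicate 1 (0.0572), male control replicate 3 (0.246) or male selenium replicate 1 (0.293). Apart from single fish left out, the muscle call ended in 2 of 9 settings, that of retina in 2 of 9, pineal in 3 of 9 and meningeal genes in 4 of 12. Without male selenium replicates 1, 2 and 4 the retina median was -0.095 and the pineal median -0.33.

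**Figure D2:**
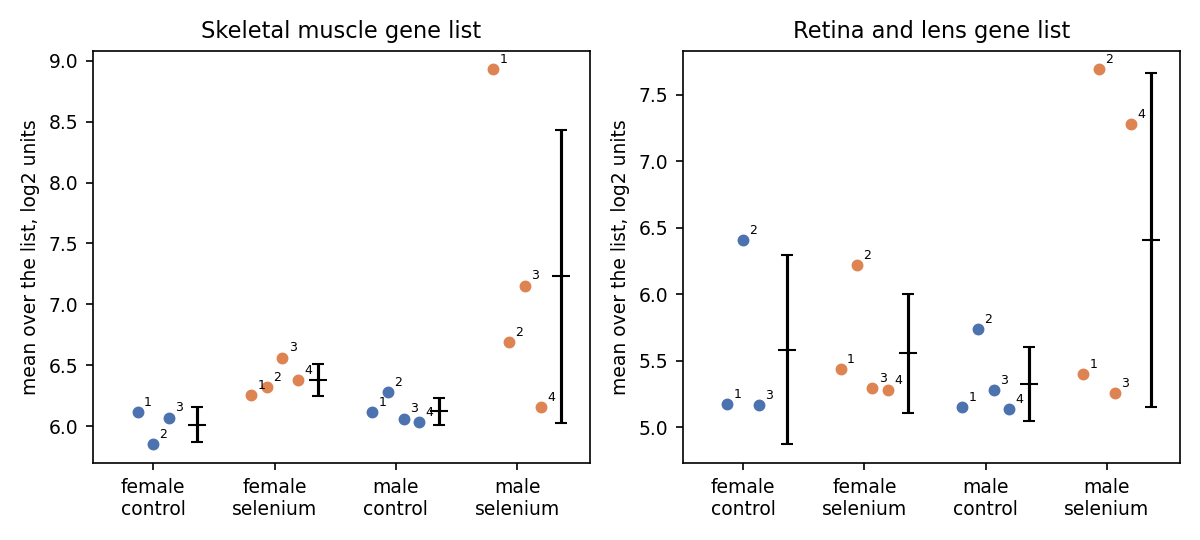
Mean over the measured genes of the skeletal muscle list (left) and the retina and lens list (right) in each fish, in log2 units, by sex and diet; numbers are the replicates, and bars are the mean and SD of the group. The muscle list reached 8.93 in male selenium replicate 1, against 5.85 to 6.28 in the 7 control fish, and the retina list reached 7.69 in male selenium replicate 2.

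Camera called 7 further lists in males on selenium, most of them of genes not particular to the brain. It called none of them with the correlation estimated from the data, where their adjusted p ran from 0.372 to 0.778. The 84 respiratory chain genes were higher as a group, with 72 members higher and a median log2 difference of 0.062, among them sdhb with 0.28 ± 0.07 and ndufc1 with 0.42 ± 0.11. The 59 mitochondrial ribosomal protein genes were higher, with 54 higher and a median of 0.096, among them mrpl41 with 0.43 ± 0.12 and mrpl37 with 0.25 ± 0.07. The 72 cytosolic ribosomal protein genes had 60 higher and a median of 0.040, with rps19 at 0.17 ± 0.08. Immediate early genes, which neurons transcribe within minutes of activity, were lower, with 25 of 30 lower and a median of -0.24. Among them npas4a stood at -0.87 ± 0.24, fosab at -0.70 ± 0.25 and egr4 at -0.66 ± 0.29. Genes of cholesterol synthesis were lower, with 12 of 13 lower and a median of -0.23, among them mvk with -0.38 ± 0.16, msmo1 with -0.50 ± 0.23 and cyp51 with -1.79 ± 0.84. Cell cycle genes had 31 of 41 lower and a median of -0.12, with nusap1 at -0.37 ± 0.17, and radial glia and astrocyte genes had 13 of 20 lower and a median of -0.086, with glula at -0.18 ± 0.07 and sox2 at -0.27 ± 0.12. Members of these lists past the test numbered 0 over all probe sets and 0 adjusted over the list alone. The muscle and retina signal above stood in the same males, at list means of 7.23 ± 1.2 (SD, n = 4) and 6.41 ± 1.26 against 6.12 ± 0.11 and 5.33 ± 0.28 in controls. When the muscle and retina list means were covariates, fewer lists than these 7 were called in males in all. The 3′ minus 5′ difference of gapdh was 0.93 ± 0.21 against 1.04 ± 0.16.

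For these lists the adjusted camera p was 8.13e-08 for the respiratory chain, 5.84e-07 for mitochondrial ribosomal proteins, 0.00283 for cytosolic ribosomal proteins, 7.16e-06 for immediate early genes, 0.000285 for cholesterol synthesis, 0.00541 for the cell cycle and 0.0318 for radial glia. Every one of these calls was lost with the correlation estimated from the data. The values were adjusted p = 0.465 with an estimated correlation for the respiratory chain and radial glia, 0.471 for mitochondrial ribosomal proteins and the cell cycle, 0.372 for immediate early genes and cholesterol synthesis, and 0.778 for cytosolic ribosomal proteins. Fry called 0 lists in males. The exact permutation p for cholesterol synthesis was 0.0286, the smallest the 70 assignments can give. The cell cycle call ended without male control replicate 1 (adjusted p = 0.0712), and that of cytosolic ribosomal proteins without male control replicate 2 (0.063) or male selenium replicate 1 (0.0962). The median of the cell cycle list was -0.071 without male control replicate 1, that of cytosolic ribosomal proteins 0.023 without male control replicate 2, and that of mitochondrial ribosomal proteins 0.053 without male control replicate 4 and 0.15 without male selenium replicate 1. The radial glia call ended without male control replicate 2 (0.131), male control replicate 4 (0.109), male selenium replicate 2 (0.0519) or male selenium replicate 3 (0.0696), and with a second quantile normalisation (0.0508). Of 12 settings other than single fish left out, it ended in 9. The call of cytosolic ribosomal proteins ended in 5, that of cholesterol synthesis in 4, that of the cell cycle in 3, and those of the respiratory chain, mitochondrial ribosomal proteins and immediate early genes in 2 each.

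Averaged over both sexes, with each sex weighted equally, the diet comparison asked for a response common to females and males. The genes with the smallest p were chek2, at a log2 difference of -0.78 ± 0.17 (SE, n = 8 and 7), mvb12ba, a subunit of the endosomal sorting complex, at 0.77 ± 0.17, and mcur1 at -0.31 ± 0.07. Others among the 20 smallest were angptl4, an inhibitor of lipoprotein lipase, at 0.77 ± 0.19, the acetoacetyl-CoA synthetase gene aacs at 0.88 ± 0.21, the retinoblastoma gene rb1 at -0.32 ± 0.08 and the AP-1 gene fosl2 at -0.35 ± 0.08. These genes, too, were chosen by their p, and not each of them moved in both sexes: mcur1 averaged 8.00 in males on selenium and 8.07 in male controls. For angptl4 and fosl2, 7 of the 8 fish on selenium lay beyond all controls of their sex. None passed: limma called 0 of 15502 probe sets, the smallest adjusted p was 0.21, and 805 had an unadjusted p under 0.05, where 775 are expected. The count was 3 without female control replicate 3, 3 without male control replicate 2 and 1 without male selenium replicate 3. Without male selenium replicates 1, 2 and 4 together it was 17.

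Muscle genes were higher over both sexes, with 33 of 36 higher, a median of 0.58 and 3 members past the test adjusted over the list alone (0 over all probe sets), among them ckma with 1.49 ± 0.40 and ckmb with 1.43 ± 0.41. Counted by fish, 7 of the 8 fish on selenium had a muscle list mean above all controls of their sex. Retina genes had 31 of 35 higher and a median of 0.50. Cell cycle genes were lower as a group, with 29 of 41 lower and a median of -0.065, among them plk1 with -0.41 ± 0.13 and hmgb2a with -0.42 ± 0.16. Mitochondrial ribosomal proteins had 40 of 59 higher, a median of 0.038 and mrps31 at 0.27 ± 0.10, and immediate early genes had 24 of 30 lower, a median of -0.13 and ier5l at -0.16 ± 0.06. These lists and retina did not move the same way in both sexes. From control to selenium the list mean of immediate early genes went from 8.245 to 8.358 in females and from 8.555 to 8.279 in males. That of mitochondrial ribosomal proteins went from 9.529 to 9.511 and from 9.469 to 9.566, and that of retina from 5.583 to 5.556 and from 5.325 to 6.407. The adjusted camera p was 1.85e-16 for muscle, 1.22e-05 for retina, 0.00641 for the cell cycle, 0.0219 for mitochondrial ribosomal proteins and 0.0432 for immediate early genes. With the correlation estimated from the data all 5 calls were lost, with adjusted p = 0.743 with an estimated correlation for each except mitochondrial ribosomal proteins, at 0.752, and fry called 0 lists. The exact permutation p of the muscle list was 0.00163, and 0.0555 adjusted over the 34 lists. Its median was 0.24 without male selenium replicate 1. The retina median was 0.24 without female selenium replicate 2, 0.25 without male selenium replicate 2, and 0.26 without male selenium replicate 4 or female control replicate 1.

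Of 13 settings other than single fish left out, the call of immediate early genes ended in 7, that of mitochondrial ribosomal proteins in 5 and that of the cell cycle in 4, and of 10 settings those of retina and of muscle ended in 3 each. With the gapdh covariate the median of immediate early genes was -0.075, that of the cell cycle -0.10, that of mitochondrial ribosomal proteins 0.055, that of retina 0.62 and that of muscle 0.42. The weaker of these calls also ended without single fish. The cell cycle call ended without female control replicate 3 (adjusted p = 0.241). The call of immediate early genes ended without female control replicate 1 (adjusted p = 0.0898) or 2 (0.0628), female selenium replicate 1 (0.0871), 2 (0.0814) or 4 (0.0613), male control replicate 3 (0.197) or 4 (0.177), or male selenium replicate 3 (0.107) or 4 (0.322). That of mitochondrial ribosomal proteins ended without female control replicate 2 (0.065) or 3 (0.052), female selenium replicate 1 (0.0699), 3 (0.153) or 4 (0.148), male control replicate 4 (0.211), or male selenium replicate 2 (0.0551), 3 (0.107) or 4 (0.13). The cell cycle median was -0.028 without female control replicate 3, -0.042 without female selenium replicate 4 and -0.029 without male control replicate 1. For immediate early genes it was -0.053 without male control replicate 3 and -0.083 without male selenium replicate 4. For mitochondrial ribosomal proteins it was 0.062, 0.023 and 0.012 without female selenium replicates 2, 3 and 4, and 0.016 without male control replicate 4.

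Whether the diet effect differed between the sexes was tested as the female effect minus the male effect. The gene with the smallest p was leo1, a subunit of the PAF1 transcription elongation complex, at -0.97 ± 0.17 (SE, n = 15 fish), with -0.56 in females and 0.42 in males. The succinate dehydrogenase gene sdhb stood at -0.53 ± 0.10, with -0.25 in females and 0.28 in males, the mitochondrial isocitrate dehydrogenase gene idh3b at -0.44 ± 0.10, the peroxisomal protease gene lonp2 at -0.51 ± 0.12 and the MYC homologue mych at 1.02 ± 0.20. None passed: limma called 0 of 15502 probe sets, the smallest adjusted p was 0.442, and 1298 had an unadjusted p under 0.05, where 775 are expected. Without male selenium replicates 1, 2 and 4 together the count was 3.

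The diet effect on the respiratory chain list was lower in females than in males, with 73 of 84 members on that side, a median difference of -0.12 and 1 member, sdhb, past the test adjusted over the list alone. Mitochondrial ribosomal proteins had a median difference of -0.11, with mrpl37 at -0.30 ± 0.10, and cytosolic ribosomal proteins -0.067, with rpl28 at -0.20 ± 0.09. Centring each array on its median moved all probe sets alike by 0.079, so that these 3 medians became -0.037, -0.033 and 0.012, and the call of cytosolic ribosomal proteins was lost (adjusted p = 0.22). Immediate early genes had a median difference of 0.25, with atf3 at 1.57 ± 0.45 and npas4a at 1.02 ± 0.35. Cholesterol synthesis had 0.31, with dhcr7 at 2.32 ± 1.1, and the glucocorticoid response 0.21, with tsc22d3, a glucocorticoid-induced leucine zipper gene, at 0.44 ± 0.14. Muscle had -0.65, with pgam2 at -1.46 ± 0.67, retina -1.23, with opn1lw1 at -2.23 ± 1.1, and pineal genes -0.77. The 3′ minus 5′ difference of gapdh had a difference of the diet effect of 0.51 (exact permutation p = 0.0878). The adjusted camera p was 1.53e-07 for the respiratory chain, 0.000212 for muscle, 0.00117 for mitochondrial ribosomal proteins, 0.00261 for immediate early genes and for retina, 0.00499 for cytosolic ribosomal proteins, 0.00965 for cholesterol synthesis, 0.0147 for the glucocorticoid response and 0.0383 for pineal genes. No call held with the correlation estimated from the data. There, the respiratory chain, immediate early genes and cholesterol synthesis had adjusted p = 0.611 with an estimated correlation, cytosolic ribosomal proteins 0.706 and the other 5 lists 0.666. Fry called 0 lists for a shift in 1 direction and 3 for a change in either direction. The exact permutation p was 0.0294 for the respiratory chain and 0.0253 for immediate early genes, each 0.333 after adjustment.

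Of 13 settings other than single fish left out, the call of cholesterol synthesis ended in 8, cytosolic ribosomal proteins in 6, the glucocorticoid response and mitochondrial ribosomal proteins in 5, and the respiratory chain and immediate early genes in 3. Of 10 settings, pineal genes lost it in 6, retina in 4 and muscle in 3. With the gapdh covariate the median was 0.11 for cholesterol synthesis, 0.092 for the glucocorticoid response, -0.046 for mitochondrial and -0.025 for cytosolic ribosomal proteins, -0.10 for the respiratory chain, 0.53 for immediate early genes, -0.88 for retina, -0.65 for pineal genes and -1.31 for muscle. Calls also ended without single fish. Muscle lost its call without male selenium replicate 1 (adjusted p = 0.192), retina without female control replicate 2 (0.095) or male selenium replicate 2 (0.0973), cholesterol synthesis without female selenium replicate 1 (0.0988), cytosolic ribosomal proteins without the same female (0.158), and mitochondrial ribosomal proteins without female selenium replicate 2 (0.0761). The glucocorticoid response lost it without female control replicate 1 (0.0963), female selenium replicate 3 (0.0725), male control replicate 4 (0.121) or male selenium replicate 3 (0.0792). Pineal genes lost it without female control replicate 2 (0.499), female selenium replicate 1 (0.0988), 3 (0.0994) or 4 (0.114), male control replicate 1 (0.072) or 4 (0.0619), or male selenium replicate 2 (0.107) or 4 (0.211). The muscle median was -0.081 without male selenium replicate 1 and -0.98 without replicate 4. For retina it was -0.65 without female control replicate 2, -0.79 without male selenium replicate 2 and -0.77 without male selenium replicate 4, and for pineal genes -0.18 without female control replicate 2 and -0.31 without male selenium replicate 4. Cholesterol synthesis had 0.20 without female control replicate 1 and 0.51 without female control replicate 3, and the glucocorticoid response 0.14 without female control replicate 1. Cytosolic ribosomal proteins had -0.041 without female selenium replicate 1 and -0.10 without female selenium replicate 4, and mitochondrial ribosomal proteins -0.18 without male selenium replicate 1.

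Female and male brains were compared at equal weight of the diets, and this was the comparison with single genes past the test. The brain of females had less dio2, the deiodinase that makes active thyroid hormone, at 7.12 log2 units against 8.17 in males, a 2.07-fold difference (log2 -1.05 ± 0.12, SE, n = 7 and 8; adjusted p = 0.00578), and less igf1, the insulin-like growth factor, by 2.06-fold (-1.05 ± 0.17, adjusted p = 0.0316). Also lower in females were hsd17b3, which makes testosterone from androstenedione, with -0.54 ± 0.09 (adjusted p = 0.0316), and inhbaa, the activin and inhibin beta A subunit, with -0.59 ± 0.10 (adjusted p = 0.0455). Neuronal genes lower in females were vamp1a of synaptic vesicles with -0.41, sncgb, a gamma synuclein, with -0.67 and the RNA-binding protein gene elavl3 with -0.79. The transcription gene leo1 was lower by 1.71-fold (-0.78 ± 0.08, adjusted p = 0.00374), with -0.29 on the control diet and -1.26 on selenium. Metabolic and membrane genes lower in females were slc25a11, a mitochondrial oxoglutarate carrier, with -0.56, pgm1 with -0.40, the calcium pump gene atp2a2b with -0.42 and the membrane skeleton gene add1 with -0.84. The rest were cacfd1 with -0.34, tspan34b with -0.80 and itprid2 with -0.54.

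Higher in females was f13a1a.1, a coagulation factor XIII A gene, by 2.36 ± 0.37 (SE, n = 7 and 8, adjusted p = 0.0291). Males read 3.87 to 4.41, a low signal, so no fold is given and the size of this log2 difference is uncertain. Also higher were the tubulin gene tuba5 by 0.79, tram2 by 0.43 and pcna, the clamp of DNA replication, by 0.24 ± 0.04 (adjusted p = 0.0455). The ribonucleotide reductase gene rrm2l, at 0.40 ± 0.07, did not pass. In all, limma called 22 of 15502 probe sets, 5 higher and 17 lower in females, which name 19 genes, 2 of the probe sets having no gene listed. At an unadjusted p under 0.05 there were 2296, where 775 are expected. For 14 of the 19 genes, dio2, f13a1a.1, igf1, hsd17b3 and pcna among them, all 7 females lay beyond all males on the same diet, and for the other 5 genes 6 females did. The genes were chosen by the test of the same values, so this describes them and adds no evidence, and the 0.0816% that chance gives holds for unselected probe sets. Other probe sets of the same genes were smaller in difference: -0.23 for leo1, -0.15 for slc25a11, -0.13 for pgm1, -0.29 for inhbaa, -0.56 and -0.27 for sncgb, of which the first passed too, and -0.57, -0.26 and -0.21 for elavl3.

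The calls of leo1 and dio2 held without any single fish, with adjusted p from 0.000942 to 0.014 for leo1 and from 0.00232 to 0.0247 for dio2. Each ended in 3 of 14 other settings. For leo1 these were the gapdh covariate (adjusted p = 0.054), the muscle and retina covariates (0.0638) and the additive model (0.0511). For dio2 they were the muscle and retina covariates (0.117) and the fits without male selenium replicates 1, 2 and 4 (0.107) or without the 4 arrays of highest retina signal (0.176). Each of the other 17 genes lost its call without 6 to 14 of the 15 fish taken singly and in 3 to 8 of the other settings, and all kept their direction. The count was 4 without female control replicate 1, 10 without female control replicate 2, 5 without female selenium replicate 1, 64 without female selenium replicate 3 and 4 without female selenium replicate 4. It was 4 without male control replicate 1, 5 without male control replicate 3, 5 without male control replicate 4, 10 without male selenium replicate 1, 4 without male selenium replicate 2, 2 without male selenium replicate 3 and 3 without male selenium replicate 4. The 3′ minus 5′ difference of gapdh was 0.40 log2 units larger in females (exact permutation p = 0.0159). With it as a covariate 5 of the 22 calls remained, and the median size over the 22 was 0.52 against 0.58, with elavl3 at -0.48. With the mean of the actin and gapdh differences as the covariate 31 probe sets were called, 20 of the 22 among them. The actin control is a muscle actin, and its 3′ probe set read 13.24 in male selenium replicate 1, against 7.79 to 8.84 in control fish. This covariate can therefore carry muscle signal and is no clean measure of RNA integrity. With the muscle and retina list means as covariates 1 was called, while all 22 kept their direction at a median of 1.02 times their log2 difference.

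**Figure D3:**
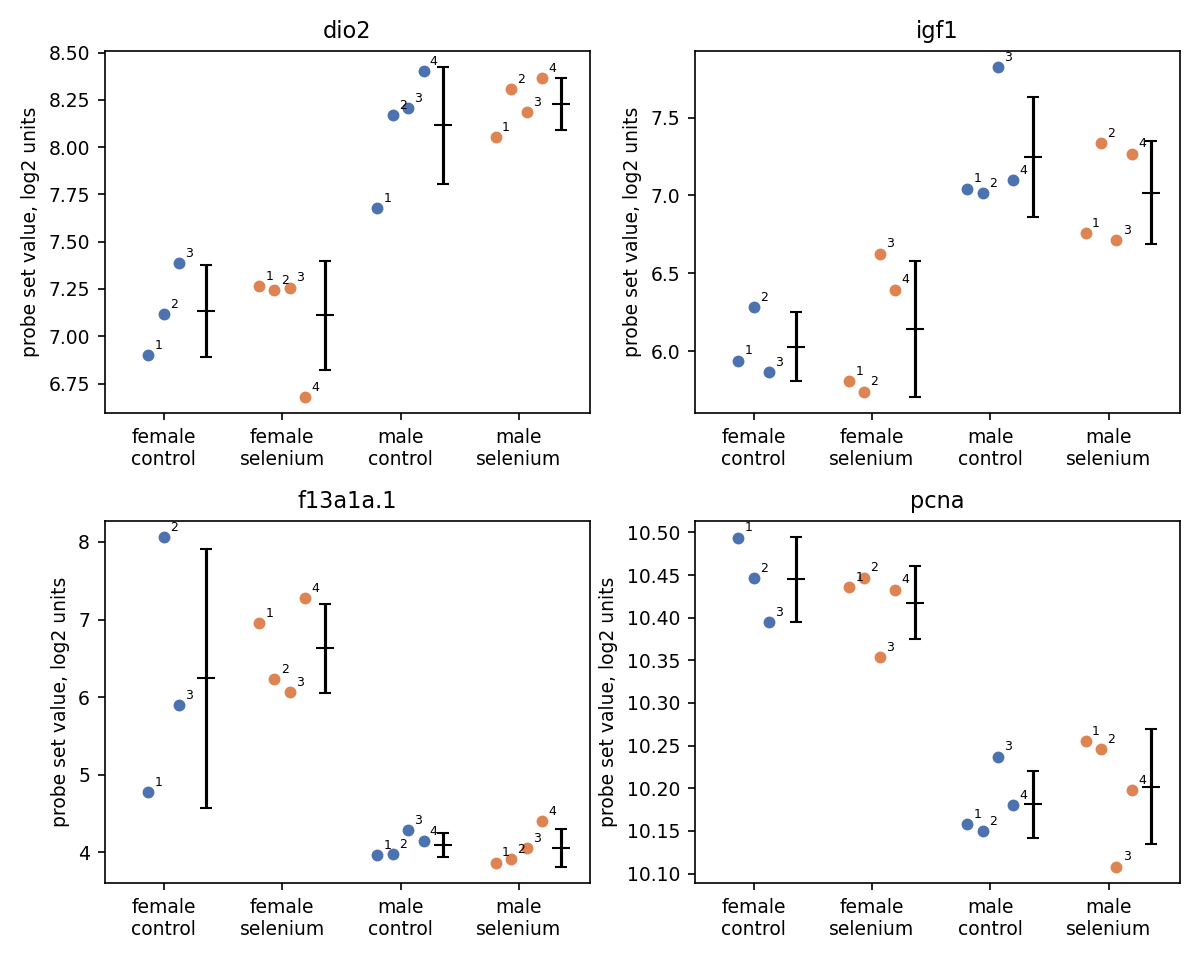
Values of the probe sets for dio2, igf1, f13a1a.1 and pcna in each fish, in log2 units, by sex and diet; numbers are the replicates, and bars are the mean and SD of each group. For each of these 4 genes all 7 females lie on 1 side of all males on the same diet, and the adjusted p of the sex difference runs from 0.00578 to 0.0455.

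**Figure D4:**
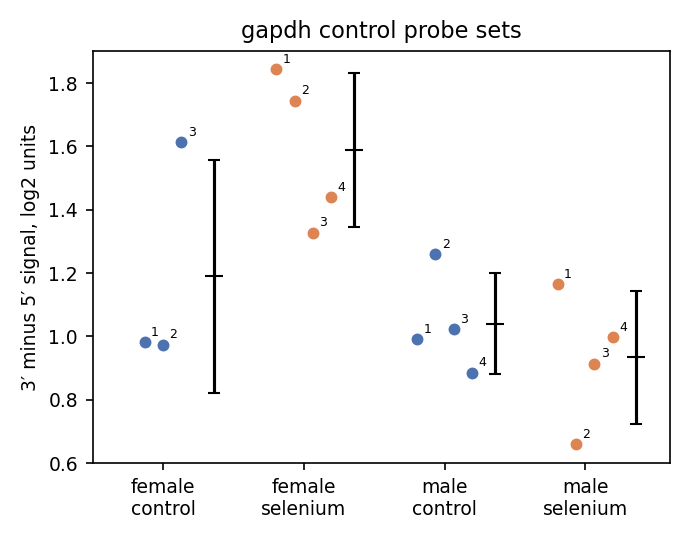
Difference between the 3′ and the 5′ control probe sets of gapdh in each fish, in log2 units, by sex and diet; numbers are the replicates, and bars are the mean and SD of the group. The difference averaged 1.59 in females on selenium and 0.93 in males on selenium.

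Camera also called lists between the sexes, none of them with the correlation estimated from the data. Cell cycle genes were higher in females, with 35 of 41 higher and a median log2 difference of 0.24, among them ccna2 with 0.44 ± 0.11 and plk1 with 0.49 ± 0.13. Of these genes 1 passed over all probe sets and 15 adjusted over the list alone. Genes of cholesterol synthesis were higher in females, with 12 of 13 higher, a median of 0.35 and 5 past the test adjusted over the list alone (0 over all probe sets), among them hmgcs1 with 0.75 ± 0.14, nsdhl with 0.68 ± 0.16 and msmo1 with 0.68 ± 0.17. Neuronal and synaptic genes were lower in females, with 22 of 29 lower, a median of -0.045, 1 past the test over all probe sets and 3 adjusted over the list alone, among them atp1a3b with -0.38 ± 0.08 and gria2b, a glutamate receptor subunit, with -0.52 ± 0.14. These counts take the brightest probe set of each gene, which for elavl3 was not the probe set called above. Microglia and macrophage genes were higher in females, with 17 of 22 higher and a median of 0.42, among them arpc1b with 0.72 ± 0.23, coro1a with 0.59 ± 0.20 and ptprc with 0.72 ± 0.25. The microglia signal lay highest in female selenium replicate 2, 0.78 above its mean over all fish, and female control replicate 1, 0.50 above. Female list means for the cell cycle were 7.10 ± 0.17 (SD, n = 3) on the control diet and 7.02 ± 0.05 (n = 4) on selenium, against 6.88 ± 0.08 and 6.78 ± 0.04 (n = 4 each) in males.

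The adjusted camera p was 1.68e-07 for the cell cycle, 0.000257 for cholesterol synthesis, 0.00062 for neuronal and synaptic genes and 0.00534 for microglia. With the correlation estimated from the data none was called: adjusted p = 0.233 with an estimated correlation for the cell cycle, 0.329 for cholesterol synthesis, 0.127 for neuronal and synaptic genes and 0.523 for microglia. Fry called 3 lists, the cell cycle (adjusted p = 0.0104), cholesterol synthesis (0.0158) and neuronal and synaptic genes (0.00814). For a change in either direction it called 14 lists, among them selenoproteins (adjusted p = 4.18e-06), which include dio2, and sex steroid and reproductive genes (5.41e-06), which include hsd17b3. The exact permutation test called 2 lists, neuronal and synaptic genes (p = 0.000408, the smallest the 2450 assignments can give, adjusted 0.0139) and the cell cycle (p = 0.00122, adjusted 0.0208). Cholesterol synthesis had an exact permutation p of 0.00449, adjusted 0.0509. These 4 calls of camera held without any single fish. Of 13 other settings, those of the cell cycle and of neuronal and synaptic genes ended in 1, cholesterol synthesis in 2 and microglia in 4. The neuronal median was -0.069 without male selenium replicate 2. The gapdh difference of 0.40 between the sexes stands beside each of them. With it as a covariate the median was 0.17 for cholesterol synthesis, 0.18 for the cell cycle, 0.30 for microglia and -0.076 for neuronal and synaptic genes, and with all probe sets of each gene that of cholesterol synthesis was 0.17.

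Camera called 11 further lists between the sexes, again none with the correlation estimated from the data. Respiratory chain genes were lower in females, with 68 of 84 lower, a median of -0.060, and 1 member, sdhb with -0.25 ± 0.05, past the test adjusted over the list alone. Glycolysis genes were lower, with 23 of 27 lower, a median of -0.041, and 1 member, pgk1 with -0.25 ± 0.05, past the test adjusted over the list alone. The glycolysis signal lay 0.25 and 0.22 above its mean over all fish in male selenium replicates 1 and 3, the fish of highest muscle signal. Every other fish lay between -0.08 and 0.04. In replicate 3 pgk1 read 11.75, against 11.52 to 11.55 in the other males on selenium. Immediate early genes had 22 of 30 lower and a median of -0.11, with egr1 at -0.47 ± 0.12 and ccn2a at -0.57 ± 0.17 but atf3 at 0.77 ± 0.22, and 3 past the test adjusted over the list alone. Circadian clock genes had 20 of 28 lower and a median of -0.062, with cry1a at -0.42 ± 0.12 but nfil3-5 at 0.47 ± 0.12, and 3 past the test adjusted over the list alone. Heat shock genes had a median of -0.059, with hsp70.3 at -0.88 ± 0.26, monoamine genes -0.055, with drd2a at -0.37 ± 0.13 and slc6a3 at -0.23 ± 0.09, and myelin genes -0.047, with cldnk at -0.23 ± 0.07 and olig2 at -0.27 ± 0.09. Endoplasmic reticulum stress genes were higher in females, with 24 of 31 higher, a median of 0.074 and 6 past the test adjusted over the list alone, among them atf4b with 0.24 ± 0.07 and manf with 0.31 ± 0.09. Cytosolic ribosomal proteins had a median of 0.048, with rps16 at 0.32 ± 0.08. Muscle genes had 35 of 36 lower in females and a median of -0.37, and retina genes a median of -0.17. Over all probe sets 0 members of these 11 lists passed. For some lists the order of the sexes changed with the diet. On the control diet the list mean in females and males was 11.5 and 11.48 for the respiratory chain, 6.907 and 6.882 for monoamine genes, and 5.583 and 5.325 for retina. On selenium these means were 11.44 and 11.56, 6.81 and 6.98, and 5.556 and 6.407. Immediate early genes read 8.245 and 8.555 on the control diet but 8.358 and 8.279 on selenium. The monoamine list shares tph1a, tph1b and tph2 with the pineal list. Relative to its mean over all fish it was highest in male selenium replicate 4 (0.28), female control replicate 2 (0.20) and male selenium replicate 2 (0.15). Pineal genes were high in those fish too, and in female selenium replicate 2, where the monoamine list lay at 0.01.

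The adjusted camera p was 1.7e-07 for the respiratory chain, 7.26e-07 for muscle, 0.00155 for cytosolic ribosomal proteins, 0.00223 for glycolysis, 0.00534 for immediate early genes, 0.0122 for retina, 0.0193 for the clock and for monoamine genes, 0.0253 for heat shock, 0.0294 for endoplasmic reticulum stress and 0.0428 for myelin. No call held with the correlation estimated from the data. The respiratory chain, glycolysis and the clock had adjusted p = 0.372 with an estimated correlation, immediate early genes 0.469, endoplasmic reticulum stress 0.517, muscle, monoamine genes, heat shock and myelin 0.523, and retina and cytosolic ribosomal proteins 0.613. Of 13 settings other than single fish left out, the myelin call ended in 8, those of heat shock, endoplasmic reticulum stress and monoamine genes in 7, immediate early genes and the clock in 6, and glycolysis, cytosolic ribosomal proteins and the respiratory chain in 3. Of 10 settings, retina lost it in 4 and muscle in 3. With the gapdh covariate the median was -0.015 for the clock, -0.074 for myelin, 0.064 for retina, -0.69 for muscle, 0.040 for monoamine genes, -0.078 for glycolysis and 0.077 for cytosolic ribosomal proteins. It was -0.068 for heat shock, 0.089 for endoplasmic reticulum stress, -0.11 for immediate early genes and -0.043 for the respiratory chain. The muscle median was -0.12 without male selenium replicate 1. The clock call ended without female control replicate 3 (adjusted p = 0.074), that of cytosolic ribosomal proteins without female selenium replicate 4 (0.0748), and that of monoamine genes without female control replicate 3 (0.154), female selenium replicate 1 (0.0653) or male selenium replicate 4 (0.0833). Retina lost its call without female control replicate 1 (0.0646) or 3 (0.0792) or male selenium replicate 2 (0.117) or 4 (0.0839). Heat shock lost it without female control replicate 3 (0.154), female selenium replicate 3 (0.103) or 4 (0.0748), male control replicate 1 (0.0862) or male selenium replicate 1 (0.0954). Endoplasmic reticulum stress lost it without female control replicate 1 (0.0751) or 2 (0.0836), female selenium replicate 1 (0.0545) or 4 (0.0839), male control replicate 2 (0.0604), or male selenium replicate 1 (0.0508) or 4 (0.0503). Myelin lost it without female control replicate 2 (0.0945) or 3 (0.0792), female selenium replicate 1 (0.0719) or 3 (0.187), male control replicate 1 (0.0775) or 4 (0.0825), or male selenium replicate 1 (0.166), 3 (0.0537) or 4 (0.0662).

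Medians of these 11 lists also moved without single fish. Immediate early genes had -0.061 without male selenium replicate 1, the clock -0.10 without female control replicate 2 and -0.097 without male selenium replicate 3, and monoamine genes -0.021 without female control replicate 3. Heat shock genes had -0.089 without female selenium replicate 1 and -0.030 without male control replicate 1. Without female selenium replicate 4 endoplasmic reticulum stress genes had 0.042, myelin genes -0.11 and cytosolic ribosomal proteins 0.027. Retina genes had -0.043, -0.47 and -0.038 without female control replicates 1, 2 and 3, -0.36 without female selenium replicate 2, and -0.37, -0.051, -0.35 and -0.052 without male selenium replicates 1, 2, 3 and 4.

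Of the 34 lists, 14 were called in none of the 5 comparisons by camera. Besides the 3 lists of selenium and antioxidant genes above, these were erythrocytes, with a smallest adjusted p of 0.0664, the proteasome (0.0824), sex steroid and reproductive genes (0.115), methionine and one-carbon metabolism (0.149), inflammation and interferon (0.175), p53 and apoptosis (0.264), metal and iron handling (0.336), pituitary hormones, endothelium and vessels, and translation factors (0.361 each), and ependyma and choroid plexus (0.507).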

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

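The weighing of the muscle and retina signal, the muscle and retina covariates and the fits without arrays of high muscle or retina signal were chosen only after the results were seen, and so were the use of the gapdh difference as a covariate and the comparison of size and SE under it; for muscle, the number of fish needed to exclude a change in all fish was raised from 1 to 2 after the values were seen.

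Muscle genes were higher in 7 of 8 fish on selenium than in all controls of their sex, most of all in male selenium replicate 1, and retina genes in 2 males on selenium. In 3 control probe sets of muscle actin, not used in the comparisons, that male read 13.24, 7.056 and 12.19 log2 units, and in the 3′ one of them 5 other fish on selenium read 9.118 to 10.22, above the 8.838 of the highest control. Against a retina change common to all fish fed selenium, 2 of the 4 males on selenium lay within the range of male controls, but a muscle change in all fish cannot be told apart from tissue in the samples, since the 1 fish below the highest male control lay 0.123 under it, a margin near the control SD of 0.111. The height of the muscle signal in male selenium replicate 1 and the retina signal are consistent with skeletal muscle or retina carried along with single dissected brains: that male stood 1.78 above the second in the muscle list, against a range of 0.430 in the 7 control fish, and was the highest of all fish for 29 of 36 muscle genes (80.6%), and 1 control fish was among the 4 highest in retina genes. Of the lists' genes, 5 of 36 muscle genes and 4 of 35 retina genes lay above the median gene in control brains, and 1 and 3 are held by another list.

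The 3′ minus 5′ difference of the gapdh control probe sets stood 0.40 higher in females on selenium than in control females (exact permutation p = 0.143) and 0.40 higher in females than in males (0.0159), which may point to RNA integrity as a source of differences. With that measure as a covariate the 22 probe sets called between the sexes kept 1.01 of their log2 difference at the median. This argues against integrity, as far as gapdh reads it, as the whole cause of their size. The measure itself differs between the sexes and its slope rests on the few fish within each group, so a part played by integrity stays open. The number past the threshold went from 22 to 5, mostly through the SE: its median went from 0.0912 to 0.122 and that of the size from 0.579 to 0.519, and the median of size over SE, 6.29, was 6.39 with the new sizes alone, 5.05 with the new SEs alone and 4.55 with both. The respiratory chain list in females kept 0.921 of its median, from -0.0454 to -0.0418, with an adjusted p that went from 0.0208 to 0.205. For other lists integrity stays open beside sex and diet: the glucocorticoid median in females went from 0.184 to 0.035, and in the difference between the sexes glucocorticoid genes went from 0.211 to 0.092, cholesterol synthesis from 0.305 to 0.106 and mitochondrial ribosomal proteins from -0.113 to -0.046.

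How often chance gives as much was tested with other assignments of the same fish. For the sex difference few splits did. Of 100 drawn, the real one included, 1 gave as many called probe sets (22 in the real one, 4 in the highest other). At an unadjusted p under 0.05, 2 gave as many (2296 and 2498), and 3 gave as many called lists (15 and 16). Other splits exceeded the real one in the last 2 counts, so chance is made unlikely and not excluded. Males mostly bore lower fish numbers than females, by the labels. Anything that goes with that order would pass the same test, and it cannot be told apart from sex here. For the diet the other counts do not exclude chance. In females 9 of 35 splits gave as many probe sets at an unadjusted p under 0.05 (1282, highest other 2208) and 29 gave as many lists (2, highest other 10). In males the counts were 7 of 35 (811, highest other 1131) and 4 for the lists (11, highest other 15). Averaged over the sexes they were 45 of 100 drawn splits (805, highest other 2112) and 64 (5, highest other 14), and for the difference of the diet effect between the sexes 14 of 100 (1298, highest other 2021) and 18 (9, highest other 11). The counts past limma's adjusted threshold say nothing of chance, since any split reaches a real count of 0: 35 of 35 in females and in males (highest other 5 and 2) and 100 of 100 averaged over the sexes and for the difference (2 and 9). The split that crosses the diets and gave 2112 probe sets, against 805, may reflect a structure among the fish other than the diet, which was not tested apart from genes that vary together.

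The female and male diet effects differed by camera's test for 9 lists, with median log2 differences of -0.116 for the respiratory chain, -0.645 for muscle, -0.113 for mitochondrial ribosomal proteins, 0.254 for immediate early genes, -1.23 for retina and lens, -0.0667 for cytosolic ribosomal proteins, 0.305 for cholesterol synthesis, 0.211 for the glucocorticoid response and -0.768 for the pineal organ. None of the 9 differed with the correlation estimated from the data.

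In 6 further control probe sets outside the comparisons a fish on selenium read above all control fish by more than their range, all at low signal. The values were 5.628 in female selenium replicate 3, and 3.164, 4.052, 6.077, 5.591 and 5.09 in male selenium replicate 2, the 5.591 belonging to a control for a fluorescent protein.

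Single fish stood apart from the other 3 of their group in 26 of 435 groups of 4, where chance gives about 1 in 20, or 21.8. The number given for each is the gap to the nearest fish over the range of the group. In female selenium replicate 2 it was 0.833 for the retina list, 0.949 for the microglia list, 0.888 for coro1a, 0.902 for lonp2, 0.899 for dhcr7 and 0.846 for slc40a1. It was 0.845 for pcna and 0.869 for tuba5 in female selenium replicate 3, 0.962 for dio2 and 0.839 for sp8b in female selenium replicate 4, and 0.9 for rps16 in female selenium replicate 1. In male control replicate 2 it was 0.93 for slc25a11, 0.943 for ranbp9, 0.92 for selenow1, 0.942 for opn1sw2 and 0.965 for aacs. It was 0.926 for npr3 and 0.924 for dhcr7 in male control replicate 1, 0.894 for igf1 in male control replicate 3 and 0.855 for cyp19a1b in male control replicate 4. Among males on selenium it was 0.886 for the mitochondrial ribosomal list and 0.883 for gpx4b in replicate 1, 0.977 for olig2 in replicate 2, 0.847 for pgk1 and 0.936 for foxo3a in replicate 3, and 0.867 for the cholesterol list in replicate 4.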

How the results depend on the processing

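Chosen only after the data were seen were the fits with the gapdh difference alone or with the muscle and retina list means as covariates, those without male selenium replicates 1, 2 and 4 or without the 4 arrays of highest retina signal, the exact permutation of the lists, and, for all lists, a second quantile normalisation and the actin and gapdh covariate, with median-centred arrays for lists other than selenoproteins.

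All 22 probe sets called between the sexes, where tested, kept their direction in every alternative. The number called in all was 94 without the dimmest 50% of probe sets (with 17 of the 22, the only ones still tested), 42 with a trended and robust prior, 57 with array weights and 185 at a threshold of 0.1 (with all 22 in each of these 3), and between 2 and 64 without 1 array. With the actin and gapdh covariate it was 31, with 20 of the 22. It was 5 with the gapdh covariate (all of the 22), 1 with the muscle and retina covariates (of the 22), 7 without the 3 males and 2 without the 4 retina arrays (with 1 of the 22 in each). In these 5 fits the 22 differences stood at a median of 1.01, 1.01, 1.02, 1.04 and 1.01 times their size. The diet count in females was 2 with the muscle and retina covariates, 1 without the 3 males, 1 without the 4 retina arrays, 1 with the 2 female groups alone, and between 0 and 5 without 1 array. In males it was 15 without the 3 males and 6 without the 4 retina arrays. Averaged over the sexes it was 1 with the muscle and retina covariates, 17 without the 3 males, 1 without the 4 retina arrays and between 0 and 3 without 1 array. For the difference between the sexes it was 3 without the 3 males. The cause of these moves was not tested, apart from the gapdh covariate above, except that fewer probe sets enter without the dimmest 50% and fewer fish without the arrays named. The 5 arrays of highest muscle or retina signal include all 4 males on selenium, so the fit without them was not run. No paired analysis was possible because each fish has a number of its own.

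The number of lists called in females, 2, was 0 without the dimmest 25% of probe sets, with median-centred arrays, with gene means, with the gapdh covariate, with all probe sets, with an estimated correlation and with fry. It was 5 with the actin and gapdh covariate, 5 without the 4 retina arrays, and between 0 and 3 without 1 array. In males, 11 became 5 with the muscle and retina covariates and 0 with an estimated correlation and fry. In each sex the exact permutation gave 0, which says nothing of the calls, since 20 of 34 lists would have to reach its smallest p. Averaged over the sexes, 5 became 8 with the actin and gapdh covariate, 0 with an estimated correlation, fry and the exact permutation, and between 3 and 6 without 1 array. For the difference between the sexes, 9 became 0 with these 3 tests. Between the sexes, 15 became 9 with the muscle and retina covariates, 9 without the 3 males, 0 with an estimated correlation, 3 with fry and 2 in the exact permutation. The cause was not tested beyond the correlation between genes, which was estimated from the data in place of the preset 0.01.

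The median of the selenoprotein list, near 0 and not called by camera in any alternative, changed sign. In females it was -0.022 without the dimmest 25%, -0.013 with quantile normalisation again, -0.004 with gene means, -0.015 with the actin and gapdh covariate, -0.066 with the gapdh covariate, -0.011 with the muscle and retina covariates, -0.047 without the 4 retina arrays, and from -0.031 to 0.021 without 1 array. Averaged over the sexes it was -0.002 without the 3 males, -0.013 without the 4 retina arrays and from -0.011 to 0.025 without 1 array. For the difference between the sexes it was 0.061 with median-centred arrays. Between the sexes it was -0.017 with the gapdh covariate, -0.022 with the muscle and retina covariates, -0.006 without the 3 males and from -0.023 to 0.017 without 1 array. The cause was not tested.

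With gene means, si:dkey-260j18.2 turned to 0.57 in males and -0.78 in the difference between the sexes, and rhoub to 0.08 in males, because other probe sets of these genes enter. With the muscle and retina means as covariates the tests of these lists are void, and they turned with the tissue lists near them. In males meningeal genes took a median of 0.055, retina -0.059, pineal -0.167 and muscle 0.036. Averaged over the sexes retina took -0.012 and muscle -0.023, in the difference between the sexes retina -0.006, pineal 0.066 and muscle 0.029, and between the sexes muscle -0.021. Without the 3 males, retina took -0.095 and pineal -0.329 in males, retina -0.056 averaged over the sexes, retina 0.128 and pineal 0.184 in the difference, and retina 0.086 between the sexes. Without the 4 retina arrays, retina took -0.048 and pineal -0.102 in males, and retina 0.17 and pineal 0.345 in the difference. Monoamine genes took 0.04 between the sexes with the gapdh covariate. These fits leave out fish of high retina signal, or remove the muscle and retina signal. The muscle signal is not gone without the 3 males: male selenium replicate 3, which stays, had a muscle list mean of 7.15, against 6.03 to 6.28 in male controls. The cause for monoamine and meningeal genes was not tested. Of 3971 values of single genes and called lists under alternatives, selenoproteins and 43 values that say nothing of stability not counted, 3425 kept their direction and side of the threshold, 528 kept the direction only and lost the call, 13 gained one and 5 turned. The single genes include those named though never called, for which keeping the side means staying uncalled. All 528 lost calls belong to called results, which held 630 and 503 of the values for lists and 285 and 261 for genes (without 1 array and in other settings). The other turned values named above are among the 43. The direction of a list is here that of its test, so 4 medians that alone crossed 0 are not among the 5: with centred arrays the respiratory chain in females and cytosolic ribosomal proteins in the difference, with the actin and gapdh covariate muscle averaged over the sexes, and with the gapdh covariate retina between the sexes. Medians of called lists moved by over 1.5 times in 58 of 630 alternatives without 1 array and in 81 of 503 others, and values of called genes in 0 of 285 and 4 of 261. Scaling alternatives shifted the median of all probe sets by at most 0.0792 log2 units.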

Other observations

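The test of the probe set with 2 levels was chosen only after its values were seen.

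Genes of metal and iron handling did not shift as a list, with an adjusted camera p of 0.504 in females, but the iron exporter gene slc40a1 passed the test adjusted over the list alone in females on selenium, at a log2 difference of -0.41 ± 0.10 (SE, n = 4 and 3), and averaged over the sexes, at -0.24 ± 0.07. It did not pass over all probe sets (adjusted p = 0.344 in females). The transferrin gene tfa stood at 0.90 ± 0.33 averaged over the sexes and did not pass. Among neuropeptide genes of the reproductive list, oxt, the oxytocin homologue, stood at -0.71 ± 0.22 averaged over the sexes, with -0.84 in females and -0.59 in males, and gnrh3 at -0.86 ± 0.31 in females. Neither passed over all probe sets or adjusted over the list alone.

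Between the sexes, the myeloperoxidase gene mpx of granulocytes stood at -1.39 ± 0.31 in females relative to males (n = 7 and 8), and the transcription factor gene foxo3a at -0.30 ± 0.08. Each was the 1 member of its list, inflammation and interferon or p53 and apoptosis, that passed adjusted over the list alone, and neither passed over all probe sets (adjusted p = 0.0781 and 0.106). The vasopressin homologue gene avp stood at 0.33 ± 0.12 and the brain aromatase gene cyp19a1b at 0.19 ± 0.08, and neither passed.

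A probe set with no gene listed, the one of smallest p averaged over the sexes, read at 2 separate levels, from 3.28 to 3.71 in 6 fish and from 7.41 to 8.54 in 9. All 7 control fish were at the high level, and so were 2 of the 8 fish on selenium, which argues against a diet effect in all fish. The gap between the levels was 3.28 times the largest spread within a level, and 36 probe sets had 2 levels more than 1 log2 unit apart with a gap more than 2 times the spread, 0 of them following the diet in every fish. An inherited variant that segregates in the strain is a candidate explanation, and it cannot be told apart from others here because no genotype is given and the ratio of 3.28 decides neither way. It did not pass the test averaged over the sexes (log2 difference -3.70, adjusted p = 0.21).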
